A study of Mus musculus with 4 samples.

How the data were processed

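Gene expression was measured in the colon of male C57BL/6 mice whose feed was rich in fat and poor in calcium, and for the treated mice also contained heme, the iron-containing pigment of red meat. Surface cells and crypt cells were cut from frozen rolls of colon by laser capture microdissection, which collects selected cells from a tissue section under a microscope. Per the labels' protocols, RNA was pooled within each diet and compartment, over 4 mice on the control diet and over 3 on heme, and 100 ng of each pool was labelled with an Affymetrix whole-transcript kit. This gave 4 arrays, with 1 array in each of the groups control surface, control crypt, heme surface and heme crypt. The surface and crypt pools of a diet came from the same mice.

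The deposited values are log2 expression values per probe set, made with RMA per the submitters' processing notes. RMA corrects the background, brings the distributions of single probes together by quantile normalization and summarises the probes of each probe set. The version of RMA and the set of arrays normalized together are not given in the sources used here. The 35556 probe sets ranged from 1.56 to 14.0 on the control surface array, from 1.58 to 13.9 on the control crypt array, from 1.45 to 13.9 on the heme surface array and from 1.29 to 13.9 on the heme crypt array. Their medians were 5.52, 5.54, 5.42 and 5.46. No detection call was used, and the number of arrays limits the precision of every value.

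Probe sets were named from the platform annotation, with symbols updated through gene identifiers to those of the GRCm38.p6 gene table. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none in that annotation. A current symbol was matched for 21698 of the 21789. The 19938 genes analysed were the means of their single-symbol probe sets. Of these genes, 999 had several probe sets, with up to 77 for a gene. A probe set with several symbols named no gene.

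Because each group holds 1 array, no test was run and no p-value or standard deviation is given. Each comparison is a difference of log2 values. A gene was counted as higher or lower when the difference was at least 2-fold (1 on the log2 scale) and at least 1 of the arrays compared reached a floor of 5.75, the median of all gene values over the 4 arrays. This is a rule of size and says nothing about variation between mice. The comparisons were heme against control in surface cells, heme against control in crypt cells, surface against crypt on each diet, and the heme effect in surface cells minus that in crypt cells. The last is also a difference of log2 values, with the floor applied to any of the 4 arrays.

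The groups, comparisons, alternatives, the rule for named genes and 29 gene lists with 414 genes were fixed before the data were examined. Of the list genes, 36 had no single-symbol probe set, and members below the floor on all 4 arrays were left out of a list. The lists cover cell type markers and pathways. The markers include those of cell types that could be carried along in a microdissected sample. The median log2 difference of each list was placed among 10000 random lists of the same size, matched on mean expression over the 4 arrays in 20 bins. The resulting percentile describes these arrays and is not a p-value. A list of 4 inhibitors of proliferation was recalled from knowledge of the study and not checked against its paper. A list of pan-epithelial genes was added after the list medians had been seen and before its own values were.

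The genes named are the 10 largest differences each way for heme against control in each compartment, the 6 largest each way for surface against crypt on the control diet, and the 5 largest each way for the remaining comparisons. Predicted or unnamed genes and genes of the microRNA, small nucleolar RNA, olfactory and vomeronasal receptor, immunoglobulin and T cell receptor families were left out of this ranking. Up to 4 members of each list with the largest differences, and all 4 inhibitors of proliferation, could be named too. Where other genes are named, this is said.

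The calculations were made in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. Cyclic loess was run in limma 3.58.1 under R 4.3.3. The size rule was tested on simulated arrays in which 1 array per group was drawn with noise. The noise had the same spread for all genes, taken from the observed heme against control differences of the comparison. Calls of unchanged genes therefore restate that spread and do not measure variation between mice. Changed genes were planted only at mean levels at least 1 above the floor on the log2 scale. Recovery of genes near or below the floor was not tested. For the surface comparison, 92.0% of genes changed by 1.5 on the log2 scale and 100.0% of those changed by 2.5 were recovered, and 120 of 10208 unchanged genes were called. For the crypt comparison, the shares were 93.0% and 100.0%, and 9 of 10158 unchanged genes were called. Of 200 simulated unchanged lists in a first run, 9.0% in surface and 2.5% in crypt lay outside the central 95% of random lists. The number was raised to 600 after these shares were seen, which gave 7.0% and 5.3%, and the other values here are from this later run. Of lists shifted by 0.5, 98.0% in surface and 100.0% in crypt lay above the 97.5th percentile. The simulated lists held random genes with independent noise, so they do not cover lists whose genes vary together. Of the 27 fixed lists with a percentile, 10 lay above the 97.5th and 7 below the 2.5th percentile for heme in surface cells. In crypt cells these numbers were 9 and 11, so a place outside the central 95% was common.

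The alternatives tried were no floor, a floor at the 75th percentile of gene values, fold thresholds of 1.5 and 3, cyclic loess on top of the deposited values, centring of each array on its ribosomal protein genes, the probe set of highest mean in place of the mean, and log2(2^value + 32), which shrinks differences of dim genes. An alternative chosen after seeing the data repeated the crypt comparison without genes at least 2-fold higher in surface than in crypt on either diet.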

Results

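Expression was profiled in surface and crypt cells of the mouse colon after 14 days on a control diet or on the same diet with heme at 0.5 µmol/g. The diet supplied 40% of its energy as fat, and the mice were 11 weeks old. Each of the 4 groups was measured as 1 pool on 1 array, so there are no replicates and none of the differences below has a replicate check. The words higher and lower, where a count or an at least 2-fold difference is given, refer to the size rule and not to a test. Across 35556 probe sets, Pearson's r between the diets was 0.979 for the surface arrays and 0.986 for the crypt arrays. Between surface and crypt it was 0.948 on the control diet and 0.937 on heme.

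The comparison of surface with crypt cells on the control diet shows how the compartments differed in mice that received no heme. Of 15 surface colonocyte markers, 14 were at least 2-fold higher in surface cells, with a median of 3.55 (percentile 100 of the random lists). Among them were the water channel gene Aqp8 (5.15), Ceacam20 (4.63), the keratin gene Krt20 (4.62) and the carbonic anhydrase gene Car4 (4.51). Ranked by log2 difference, Ly6g (6.69) came before the proton pump gene Atp12a (6.21), Cyp2d12 (5.96), the acute-phase gene Saa1 (5.78), the peptide transporter gene Slc15a1 (5.56) and Nlrp9b (5.27). Crypt cells had more Reg4 (-4.93), the oxidase gene Nox1 (-4.38), Clca3a2 (-4.29), Clca3b (-3.96), the fucosyltransferase gene Fut9 (-3.91) and D17H6S56E-5 (-3.82). For 9 of these 12 genes the lower of the compared values lay below the floor, so the sizes and ranks are uncertain, and with log2(2^value + 32) Ly6g differed by 5.63, Cyp2d12 by 4.24 and Fut9 by -2.10.

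Markers of the crypt base and its dividing cells lay on the crypt side. All 14 crypt base and progenitor markers were at least 2-fold lower in surface cells, with a median of -2.25, including Cdca7 (-3.18), the stem cell receptor gene Lgr5 (-2.99) and Lrig1 (-2.84). All 5 deep crypt secretory markers were lower (median -2.45), as were 20 of 21 mitotic genes (median -1.87), 17 of 23 DNA replication genes (median -1.83) and 12 of 13 ribosome biogenesis genes (median -1.75). Examples were Ccna2 (-2.78), Mki67 (-2.56), the helicase subunit gene Mcm6 (-3.00) and Nop56 (-2.54). The medians of these lists lay at percentile 0 of the random lists. Of the 10 goblet cell markers, 3 were higher, among them Zg16 (3.28) and Tff3 (2.20), and 3 were lower, among them Spink4 (-2.99). Their median was -0.45 and became 0.79 when the arrays were centred on ribosomal protein genes. Spink4 and Agr2 (-2.04) are on both the goblet cell and the deep crypt secretory lists. Of 9 enteroendocrine markers, Gcg (-2.94) and Insl5 (-1.86) were lower, and Tph1 (1.44) and Sct (1.24) were higher.

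Transport, detoxification and defence genes lay on the surface side. Of 15 ion and water transport genes, 9 were higher in surface cells and 3 lower (median 2.14), and of 10 xenobiotic metabolism genes 8 were higher and 1 lower (median 2.57). Of 9 inflammation and antimicrobial genes, 7 were higher and none lower (median 2.26). The counts were 5 and 1 of 8 regenerative and wound-associated genes (median 1.29), and 6 and 3 of 13 genes of junctions and transmembrane mucins (median 0.98). Members included the sodium-proton exchanger gene Slc9a3 (4.80), the chloride exchanger gene Slc26a3 (4.47), Cyp2d34 (4.35), Duoxa2 (2.83), Sprr1a (3.12) and Cldn4 (3.29). Cldn2 (-3.57) and Cldn15 (-2.74) were lower. Of 16 heme and iron genes, 4 were higher, among them the iron exporter gene Slc40a1 (3.62), the folate transporter gene Slc46a1 (2.74) and Heph (2.08). The transferrin receptor gene Tfrc (-1.97) was lower. The interferon regulator gene Irf7 (3.97), Ifit1 (3.62) and Psmb8 (1.07) were the 3 members higher of 10 antigen presentation and interferon genes. Of the 4 inhibitors of proliferation recalled for this study, Bmp2 (3.99) and Il15 (2.75) were higher, while Ihh differed by 0.23 and Wif1 by 0.03, with all Wif1 values below the floor. Of the list members named for this comparison, Lgr5, Tph1, Sct, Lum, Bmp2, Sprr1a, Ifit1 and Cldn2 had their lower value below the floor, and with log2(2^value + 32) Sct, and above the floor Psmb8 and Plvap, did not pass the size rule. With it, 16 mitotic, 13 DNA replication and 11 ribosome biogenesis genes were lower.

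In all, 1301 of 10864 genes were at least 2-fold higher in surface than in crypt cells on the control diet and 1464 were lower. Ribosomal protein genes themselves were lower in surface cells, with a median level over 59 genes of 9.54 against 10.8 in crypt cells. Centring on them moved the median difference of all genes to 1.26 and the split to 7537 higher and 120 lower. Under that scaling the medians of the crypt base (-0.77), mitotic (-0.63), DNA replication (-0.59) and ribosome biogenesis (-0.51) lists were nearer to 0 and still negative. The smooth muscle and fibroblast markers had a median of -0.34 (0.93 after ribosomal protein centring), the immune markers 0.18, the endothelial markers 0.13 and the tuft cell markers 0.27. Of 14 smooth muscle and fibroblast markers, 5 were lower, among them Lum (-2.19), Dcn (-2.01) and Acta2 (-1.36), and Pdgfra (1.32) was higher. Of 8 endothelial markers, Kdr (1.44) and Plvap (1.11) were higher.

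The main question of the study was how dietary heme changes the surface and the crypt epithelium. In surface cells, heme was accompanied by higher RNA levels of 18 of 23 antioxidant and detoxification genes of the NRF2 response. Slc7a11, the cystine importer gene that supplies glutathione synthesis, differed by 6.05, from 4.21, which is below the floor, to 10.3. Hmox1, which encodes the heme-degrading heme oxygenase, differed by 5.39 (42.0-fold), and the neutral amino acid transporter gene Slc6a19, whose control value was also below the floor, by 5.26. With log2(2^value + 32) the order changed, with Hmox1 at 4.87, Slc7a11 at 4.64 and Slc6a19 at 4.35. Abcc2, encoding an export pump for conjugates, differed by 4.42, the amino acid transporter gene Slc1a4 by 4.25, and the reductase genes Ptgr1 by 4.20, Cbr3 by 4.11, Nqo1 by 4.09 and Akr1b8 by 3.99. The malic enzyme gene Me1, a source of NADPH, differed by 3.96.

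On the other side, Slc17a4 (-3.38) and the sulfate transporter gene Slc13a1 (-3.33) had the lowest values on heme relative to control in surface cells. Ifit1bl2 (-3.28) and Trim30d (-3.20), the deiodinase gene Dio1 (-3.09), the sterol exporter gene Abcg5 (-3.08), Slc46a1 (-2.94) and the manganese exporter gene Slc30a10 (-2.88) were also lower. So were Duox2 (-2.81), encoding an oxidase that releases hydrogen peroxide, and Duoxa2 (-2.74), encoding its maturation factor. In total, 372 of 10282 genes were at least 2-fold higher and 207 were lower, and 141 and 55 differed at least 3-fold. The heme values of Slc13a1, Ifit1bl2, Trim30d and Abcg5 lay below the floor, and with log2(2^value + 32) their differences were -2.30, -1.89, -2.44 and -1.98.

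By list, 18 of 23 genes of the NRF2 antioxidant response were higher in heme surface cells and none was lower. Their median was 1.63, at percentile 100 of the random lists. Besides the genes above, they included the glutathione synthesis genes Gclc (3.29) and Gclm (2.66), named for their function after their values were seen. Of 16 heme and iron genes, Hmox1, Tfrc (1.98) and the ferritin gene Ftl1 (1.29) were higher and Slc46a1 was lower, with a median of 0.48 (percentile 99.98). Of 21 genes of fatty acid oxidation and PPAR alpha, 9 were higher and none lower, with a median of 0.81 (percentile 100). Pdk4 (3.80), encoding a kinase that restrains pyruvate oxidation, Acot2 (2.96), Vnn1 (1.57) and Acadl (1.55) led this list. Of 16 cholesterol synthesis genes, Idi1 (1.40) and Lss (1.02) were higher, with a median of 0.59 (percentile 99.96). Of 12 heat shock and unfolded protein genes, Asns (1.08) was higher, and the median was 0.66 (percentile 99.99).

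Genes linked to wounding and growth factor signalling also had higher medians in heme surface cells. Plaur (2.55), Sprr1a (2.15) and Anxa1 (1.02) were the 3 members higher of 8 regenerative and wound-associated genes (median 0.88, percentile 100). Of 9 EGF receptor ligands and receptors, Nrg1 was higher by 1.68 and Ereg, encoding epiregulin, by 3.54 from a control value of 5.01, below the floor (2.66 with log2(2^value + 32)), while Hbegf and Btc each differed by 0.98, and the median was 0.42 (percentile 99.4). Of 10 xenobiotic genes, Abcc2, Cyp2c65 (1.63) and Abcg2 (1.03) were higher and Sult1a1 (-1.35) was lower, with a median of 0.50 (percentile 99.1).

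The medians of interferon, defence and tuft cell genes lay below 0 in heme surface cells. Irf7 (-2.20), the immunoproteasome gene Psmb8 (-1.40), Ifit1 (-1.35) and the peptide transporter gene Tap1 (-1.09) were the 4 members lower of 10 antigen presentation and interferon genes, and the list median was -0.47 (percentile 0.06). Of 9 inflammation and antimicrobial genes, Duox2, Duoxa2 and Ang4 (-1.27) were lower and the prostaglandin synthase gene Ptgs2 (1.91) was higher. Their median was -0.75 (percentile 0). Among 6 tuft cell markers, Dclk1 (-1.34), Trpm5 (-1.17) and Sh2d6 (-1.07) were lower, with a median of -1.12 (percentile 0) that moved to -0.53 with no floor. Muc1 (-1.72) was the 1 member lower of 13 genes of junctions and transmembrane mucins (median -0.24, percentile 1.03). The immune markers had a median of -0.086 (percentile 32.5), the endothelial markers 0.04 (percentile 71.0) and the smooth muscle and fibroblast markers -0.44 (percentile 0), with no member past the size rule.

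The study concerned feedback inhibitors of proliferation. The 4 genes examined as such were recalled from knowledge of the study and not checked against its paper, and the list is not independent evidence of a direction. In heme surface cells, the cytokine gene Il15 fell by 2.27 on the log2 scale, from 8.55 to 6.29, and the hedgehog ligand gene Ihh fell by 1.16, from 8.33 to 7.17. Bmp2 differed by -0.19 and the Wnt inhibitor gene Wif1 by -0.23, with Wif1 between 5.17 and 5.40 on the 4 arrays, below the floor. In crypt cells, the differences were -0.32 for Il15, -0.03 for Ihh, 0.05 for Bmp2 and -0.08 for Wif1. The 3 members above the floor had a median of -1.16 in surface cells and -0.03 in crypt cells.

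Among markers of the epithelium itself, 3 of 15 surface colonocyte markers were higher in heme surface cells, namely Tmigd1 (2.28), the bile acid exporter subunit gene Slc51b (1.40) and Clca4a (1.02), with a median of 0.38 (percentile 97.0). None of 14 crypt base and progenitor markers passed the size rule, and their median was -0.33 (percentile 0.35). None of 21 mitotic genes passed it either (median 0.27, percentile 99.9), with Ccna2 at 0.88. Of 23 DNA replication genes, the ribonucleotide reductase gene Rrm2 (2.14) was higher (median 0.16, percentile 98.2). The medians of the goblet cell (0.00), deep crypt secretory (0.08), enteroendocrine (0.06), ribosome biogenesis (-0.05), p53 target (0.05), signalling (-0.02) and ion transport (0.14) lists lay within the central 95% of the random lists. Members of these lists past the size rule included Spink4 (1.56), Reg4 (1.23), Kit (-1.03), Gcg (1.54), Insl5 (1.03), Chga (-1.19), Fas (-1.30), Fzd5 (-1.10) and the sodium channel gene Scnn1g (1.68). Kcnma1 (1.03) rested on a pair of probe sets at 0.19 and 1.87. Of the list members named for heme surface cells, Trpm5, Rrm2, Vnn1, Fas, Ang4, Tap1, Kcnma1 and Muc1 also had their lower value below the floor, and with log2(2^value + 32) Trpm5, Fas, Ang4, Tap1 and Kcnma1 did not pass the size rule. Of those above the floor, neither did Reg4, Kit, Insl5, Sh2d6, Lss, Asns and Fzd5.

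**Figure D1:**
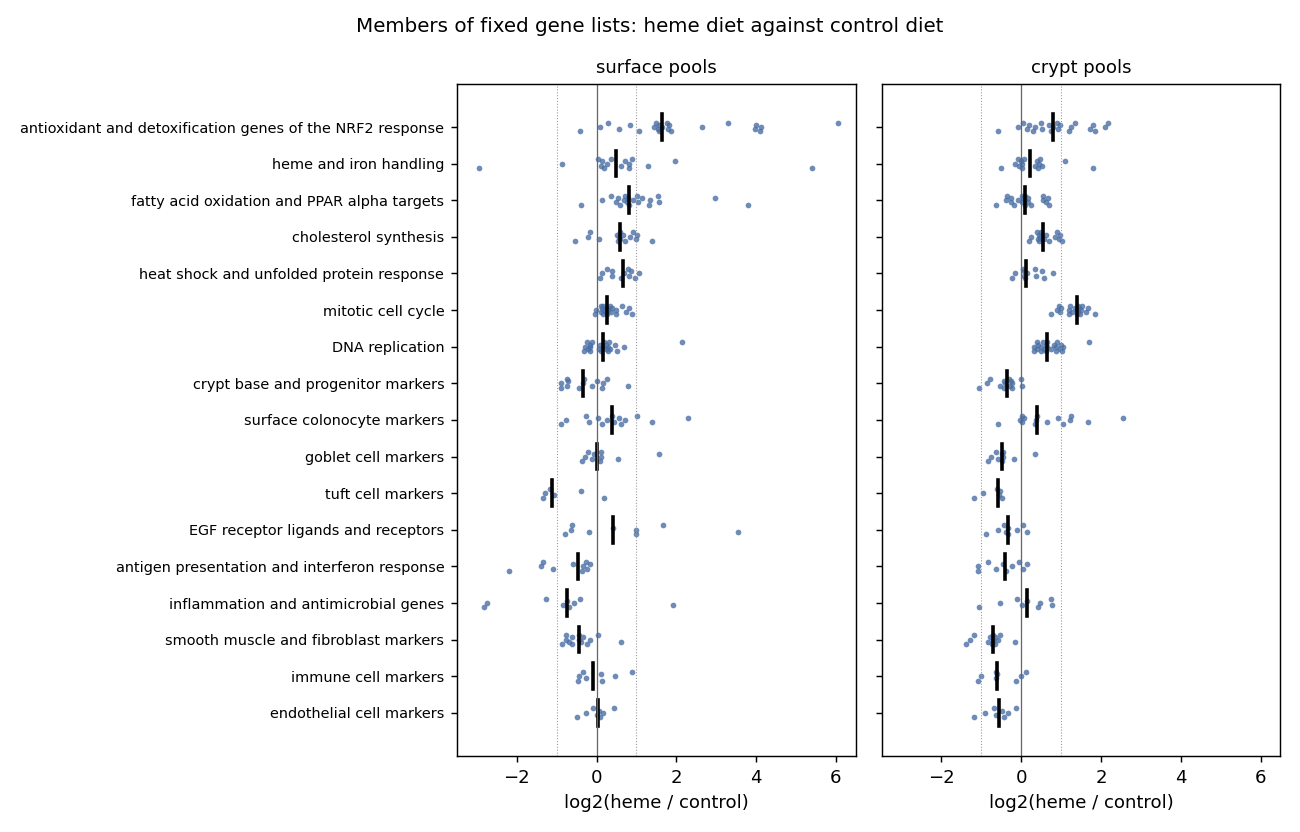
Log2 difference of heme against control for each member (points) of 17 of the gene lists, in surface pools on the left and crypt pools on the right, with the list median as a black bar and dotted lines at 2-fold. The median of the NRF2 list was 1.63 in surface and 0.81 in crypt cells, and that of the mitotic list 0.27 in surface and 1.39 in crypt cells.

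In crypt cells, heme was accompanied by higher levels of genes of dividing cells. Of 21 mitotic genes, 16 were at least 2-fold higher, all 21 were above 0, and the median was 1.39 (2.63-fold, percentile 100). The spindle checkpoint kinase gene Bub1 differed by 1.86, Birc5 by 1.67, Kif20a by 1.62 and Ccna2 by 1.51. Of 23 DNA replication genes, Rrm2 (1.70), the nuclease gene Fen1 (1.06) and the thymidine kinase gene Tk1 (1.01, from a pair of probe sets at 0.65 and 1.37) were higher, and all 23 were above 0, with a median of 0.64 (percentile 100). No ribosome biogenesis gene passed the size rule, and their median was 0.29 (percentile 99.6). In the same pool, the marker medians of smooth muscle and fibroblasts (-0.72), immune cells (-0.62) and endothelium (-0.55) lay below 0, each at percentile 0. The members lower by the size rule included Lum (-1.38), Vim (-1.27), Dcn (-1.17), H2-Aa (-1.08), Csf1r (-1.02) and Cd34 (-1.20), and the pan-epithelial genes had a median of -0.044 (percentile 28.3).

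Among single genes in crypt cells, Aqp8 was higher by 2.55, Ly6g by 2.39, the fatty acid desaturase gene Scd1 by 2.22, Cbr3 by 2.19, Me1 by 2.09, Slc9a3 by 2.05 and Atp12a by 1.98. The spindle gene Hmmr (1.93), Aldh1a7 (1.90) and the mitotic kinase gene Pbk (1.89) followed. At the other end, the gasdermin genes Gsdmc2 and Gsdmc4 differed by -4.05 and -3.52. B3gnt6, encoding an enzyme of mucin glycan synthesis, differed by -2.62, Plet1 by -2.60, the chemokine gene Ccl6 by -2.08 and the pentraxin gene Mptx1 by -1.91. The sulfotransferase genes Sult1c2 (-1.89) and Sult1a1 (-1.87), B3galt2 (-1.80) and the endothelin gene Edn1 (-1.76) were also lower. In total, 187 of 10491 genes were higher and 125 were lower, and 32 and 15 differed at least 3-fold. The lower value lay below the floor for Ly6g, Me1, Atp12a, Hmmr, B3galt2 and Edn1, with Ly6g at 1.59 and Edn1 at -1.14 under log2(2^value + 32). Centring on ribosomal protein genes moved the median of all genes in crypt cells from 0.01 to 0.16 and the split to 242 higher and 64 lower.

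The NRF2 list also had a median above 0 in the heme crypt pool, as did the surface colonocyte markers (0.39). Of 23 NRF2 genes, 8 were higher and none lower, with a median of 0.81 (percentile 100), and Gsta3 (1.86) and Slc7a11 (1.80) were among them. Hmox1 (1.81) and Tfrc (1.10) were the 2 members higher of 16 heme and iron genes (median 0.21, percentile 98.6). All 16 cholesterol synthesis genes were above 0, with a median of 0.54 (percentile 100), and Idi1 (1.02) passed the size rule. Of 10 xenobiotic genes, Cyp2c65 was higher and Sult1a1 lower (median 0.25, percentile 98.9). The medians for fatty acid oxidation (0.09), heat shock (0.11), inflammation (0.16), regeneration (0.13), p53 targets (-0.19) and junctions (-0.09) lay within the central 95% of random lists, although Il18 (-1.07) and Sprr1a (1.02) passed the size rule. Of the list members named for heme crypt cells, Rgs13, Lum, Hmox1, Slc7a11, Il18, Sprr1a and Cyp2c65 had their lower value below the floor, and with log2(2^value + 32) Rgs13, Lum, Il18 and Sprr1a did not pass the size rule. Of those above the floor, neither did Clca4a, Lgr5, Csf1r, H2-Aa, H2-Ab1, Cd34, Fen1, Tk1, Idi1, Bmp4 and Id1.

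In the heme crypt pool, the medians of surface genes lay above 0 and those of crypt base and secretory genes below 0, with few members past the size rule. Aqp8, Tmigd1 (1.68), Krt20 (1.25), Slc26a3 (1.22) and Clca4a (1.04) were the 5 members higher of 15 surface colonocyte markers (median 0.39, percentile 99.99). Of 15 ion and water transport genes, Aqp8, Slc9a3, Atp12a and Slc26a3 were higher (median 0.41, percentile 100). Lgr5 (-1.07) was the 1 member lower of 14 crypt base and progenitor markers, whose median was -0.36 (percentile 0.01), and Rnf43 (-0.86) and Ascl2 (-0.79) did not pass the size rule. No goblet cell marker passed it (median -0.48, percentile 0), nor did deep crypt secretory (median -0.37, percentile 1.19) or enteroendocrine markers (median -0.53, percentile 0.04). Of 6 tuft cell markers, Rgs13 (-1.17) was lower (median -0.58, percentile 0.09). In the same pool, the stromal, immune and endothelial marker medians were -0.72, -0.62 and -0.55.

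The medians of the signalling and antigen presentation lists in crypt cells were below 0, as were those of the stromal (-0.72) and immune (-0.62) markers. Of 17 Wnt, BMP and hedgehog genes, Bmp4 (-1.18) was lower and Id1 (1.02) higher, with a median of -0.32 (percentile 0.06). The EGF receptor list had a median of -0.34 (percentile 0.72) with no member past the size rule. The class II genes H2-Ab1 (-1.08) and H2-Aa (-1.08) were the 2 members lower of 10 antigen presentation and interferon genes, whose median was -0.41 (percentile 0.02). The immune marker list also holds H2-Aa.

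**Figure D2:**
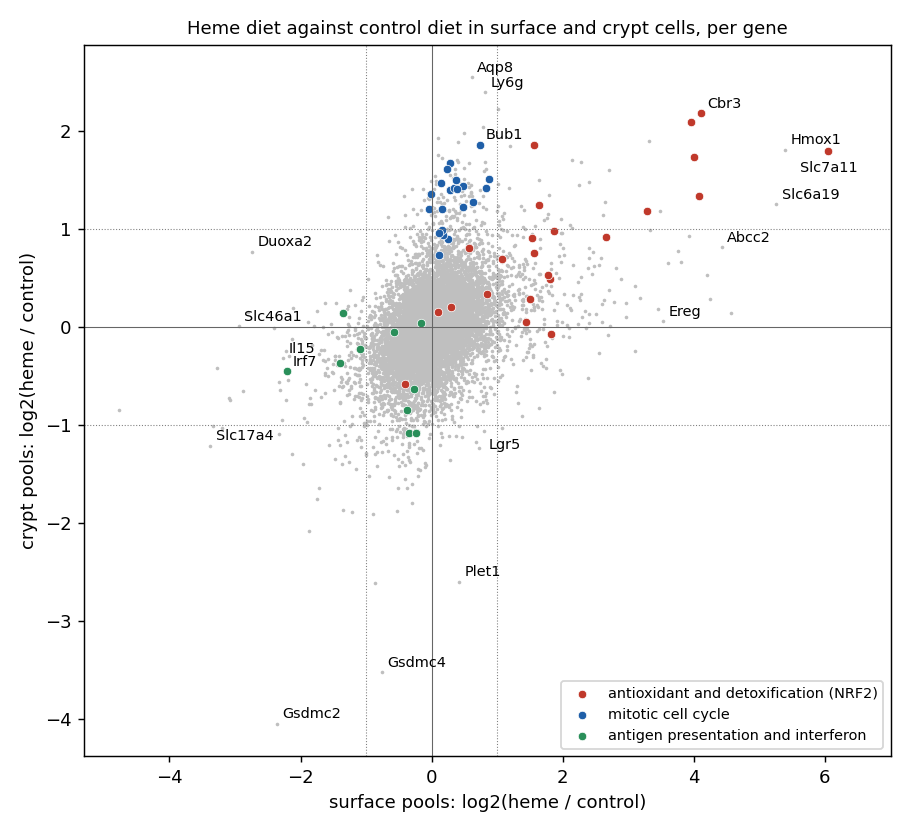
Log2 difference of heme against control for each gene in surface pools (horizontal axis) and crypt pools (vertical axis), 1 point per gene, with members of 3 lists in colour and dotted lines at 2-fold. Slc7a11 lies at 6.05 in surface and 1.80 in crypt cells, Gsdmc2 at -2.36 and -4.05, and Bub1 at 0.74 and 1.86.

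The heme effects of the compartments, which share mice but no array, were then set against each other. Hmox1, Slc7a11, Cbr3 and Me1 were higher in both, and Slc17a4 was lower in both (-3.38 and -1.21). Across 11147 genes, Pearson's r was 0.41 and Spearman's rho 0.41, and genes are not independent replicates. Both compartments had higher values for 43 genes, of 375 in surface and 188 in crypt cells, where independent lists would share 6.32. Both had lower values for 31 genes, of 210 and 129, where 2.43 would be shared, and 1 gene passed the size rule in opposite directions. For the genes higher in both, surface cells carried into the heme crypt pool, taken up below, were not separated from an effect in crypt cells.

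The heme effect in surface cells exceeded that in crypt cells by 4.26 for Slc7a11, 4.01 for Slc6a19, 3.96 for Slc1a4, 3.67 for Ptgr1 and 3.61 for Abcc2. The control values of Slc7a11 lay below the floor. Among the named genes, with log2(2^value + 32) Slc6a19 (3.72), Hmox1 (3.61), Slc1a4 (3.46) and Abcc2 (3.39) came before Slc7a11 (3.30). The surface effect was below the crypt effect for Duoxa2 (-3.51), Duox2 (-2.96), Slc46a1 (-2.95), Ifit1bl2 (-2.85) and the bicarbonate transporter gene Slc4a4 (-2.40). The difference between these effects was at least 2-fold and positive for 12 of 23 NRF2 genes (median 1.21), 8 of 21 fatty acid oxidation genes (median 0.78) and 3 of 9 EGF receptor genes (median 0.53), among them Pdk4 (3.14) and Ereg (3.48, or 2.63 with log2(2^value + 32)). It was negative for 11 of 21 mitotic genes (median -1.01), including Birc5 (-1.40), for 5 of 9 inflammation genes (median -1.17), where Ptgs2 (1.90) was positive, and for 4 of 15 ion transport genes (median -0.26), where Scnn1g (1.28) was positive. With log2(2^value + 32), the counts of these 6 lists were 12, 6, 2, 9, 2 and 2, in this order. The difference between the effects was -1.94 for Il15, -0.24 for Bmp2 and -1.13 for Ihh, which did not pass the size rule with log2(2^value + 32). At least 1 of the 4 values of Slc6a19, Hmox1, Abcc2, Ifit1bl2, Pdk4, Ereg, Birc5, Ptgs2, Scnn1g, Il15 and Bmp2 lay below the floor. In all, the difference was positive for 367 of 11147 genes and negative for 242, and 308 and 312 after centring on ribosomal protein genes, which moved the median of all genes to -0.11. Without replicates, no interaction could be tested.

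On the heme diet, the contrast between surface and crypt cells resembled that on the control diet. Clca4b (5.40), Nlrp9b (5.12), Ly6g (5.11), the dehydrogenase gene Dhrs9 (4.75) and Slc6a19 (4.73) were highest in surface relative to crypt cells. Nox1 (-4.58), Clca3a2 (-4.26), Nxpe2 (-3.98), D17H6S56E-5 (-3.83) and Bub1 (-3.67) were lowest. For 6 of these 10 genes the lower value lay below the floor, with Nlrp9b at 3.11 and Bub1 at -2.71 under log2(2^value + 32). All 15 surface markers were higher (median 3.39), and 12 of 14 crypt base markers (median -1.99), 21 of 21 mitotic genes (median -2.94) and 21 of 23 DNA replication genes (median -2.33) were lower. Fatty acid oxidation genes (15 of 21 higher, median 1.31), NRF2 genes (12 higher and 4 lower of 23, median 1.04) and EGF receptor genes (7 of 9 higher, median 1.40) lay on the surface side, with Pdk4 at 4.67 and Ereg at 3.51 (3.85 and 2.65 with log2(2^value + 32)). Of 9 inflammation genes, Ptgs2 (4.71), Saa1 (4.61) and Il18 (2.91) were higher, and the list had a median of -0.19 but a mean of 1.20. That median changed sign to 0.13 with no floor, 2.91 with the floor at the 75th percentile and 1.41 after ribosomal protein centring. Bmp2 differed by 3.75, Il15 by 0.81 and Ihh by -0.90, the last becoming 0.26 after ribosomal protein centring. The crypt values of Pdk4, Ereg, Ptgs2, Il18, Bmp2 and Il15 lay below the floor.

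On heme, 1637 of 10698 genes were higher in surface cells and 1763 lower, or 6917 and 319 after centring on ribosomal protein genes, which moved the median of all genes to 1.16. Across 11147 genes, the surface to crypt differences on the diets had a Pearson's r of 0.89. Both diets had 1070 genes higher, where independent lists would share 193, and 1209 lower, where 238 would be shared, and 5 genes were opposite. Values of Ly6g, the Clca3 and Clca4 genes, Gsdmc2 and Gsdmc4, Aldh1a7 and the sulfotransferases and glutathione transferases are uncertain, since near-identical family members may share their probes. The lists for red blood cells and for enteric neurons and glia had no member above the floor.

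**Figure D3:**
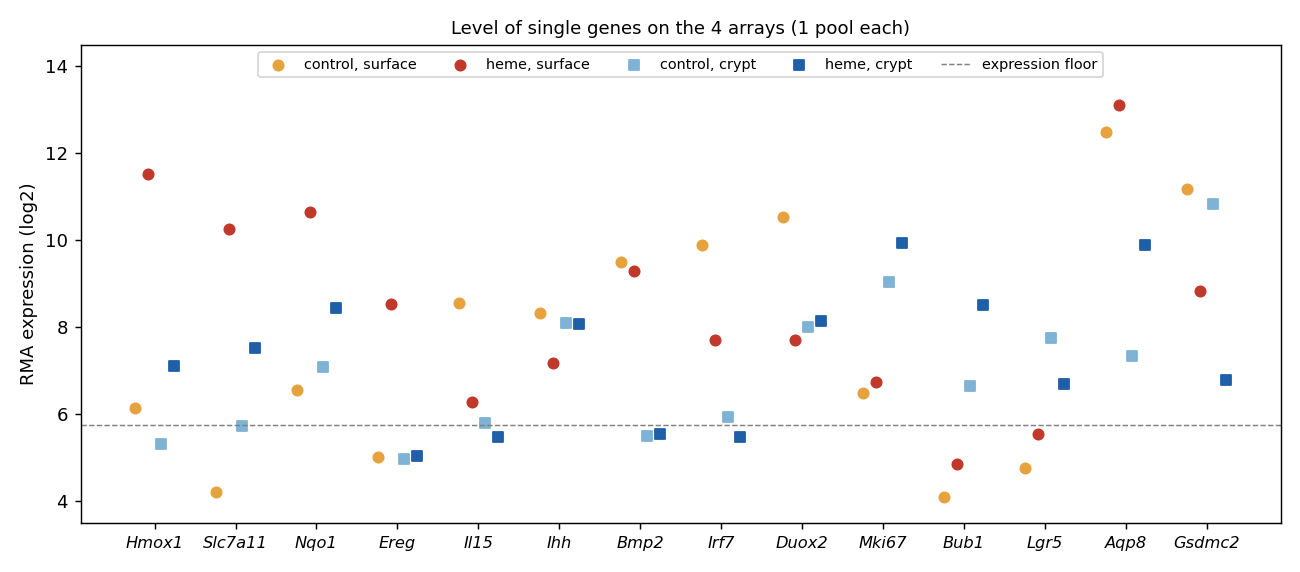
RMA expression (log2) of 14 genes on the 4 arrays, with circles for surface and squares for crypt pools, lighter colours for control and darker colours for heme, and a dashed line at the floor of 5.75. Hmox1 went from 6.14 to 11.5 in surface and from 5.31 to 7.12 in crypt cells, and Il15 from 8.55 to 6.29 in surface cells.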

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

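A set of genes had heme effects of opposite direction in surface and crypt cells, each of at least 1.5-fold. These differences were not tested, because each group is 1 array. There were 34 such genes among 11147, against 401 with the same direction in both compartments. Of the named genes, Duoxa2 was lower on heme in surface cells (-2.74) and higher in crypt cells (0.77), a difference of -3.51. Nos2 was at -0.83 and 0.74, a difference of -1.57, with its control surface value (5.89) alone above the floor. Bmp4 was at 0.68 in surface and -1.18 in crypt cells, a difference of 1.86. Lgr5 was at 0.79 and -1.07, a difference of 1.86, with both surface values (4.76 and 5.55) below the floor. The lipid uptake gene Cd36 was at 0.91 and -0.63, a difference of 1.54, and the lysozyme gene Lyz2 at 0.89 and -0.61, a difference of 1.51. Lyz2 is on the immune marker list, and Pdgfra of the stromal list, named after its values were seen, was in the set too (0.61 and -0.72). The stromal and immune marker medians in crypt cells were -0.72 and -0.62, so that a different share of such cells is not excluded for these genes.

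The EGF receptor list also had medians of opposite direction, 0.42 in surface and -0.34 in crypt cells, both outside the central 95% of random lists, and the median of the difference over its 9 members was 0.53. Of the probe sets without a single gene name, which entered none of the comparisons, 5660 reached the floor in surface cells, and 215 of these were at least 2-fold higher on heme and 181 lower. In crypt cells 5545 reached it, and 42 were higher and 185 lower.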

How the results depend on the processing

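Each comparison sets 1 array against 1 array, or for the difference of heme effects uses each of the 4 arrays once, so no array could be left out. The surface and crypt pools of a diet share mice, but 1 such pair per diet gives no spread. Over all 4 arrays, a paired fit of compartment blocked by diet, or of diet blocked by compartment, was possible with 1 residual degree of freedom and was not run. Cyclic loess and the probe set of highest mean left all counts within 1.5 times of the reported ones and reversed nothing. Without surface-enriched genes, an alternative chosen after seeing the data, the crypt comparison gave 150 genes higher and 94 lower. With each list median counted once per alternative, 737 results moved by less than 1.5-fold, 64 moved by more and 4 reversed. For named genes, counted the same way, these numbers were 1993, 296 and 3. Centring on ribosomal protein genes gave 50 of the 64 and 225 of the 296, and 2 of the 4 and all 3 that reversed. Reversed means a change of sign of a gene difference of at least 2-fold or of a list median outside the central 95% of random lists. Smaller values also changed sign, 25 times for list medians and 14 times for named genes, and these are counted by how far they moved.

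With a 1.5-fold threshold, the genes higher and lower were 1084 and 814 for heme in surface cells, 618 and 587 for heme in crypt cells, 2193 and 2739 for surface against crypt on control, 2669 and 2951 on heme, and 1126 and 912 for the difference of effects. With a 3-fold threshold they were 141 and 55, 32 and 15, 660 and 528, 834 and 769, and 120 and 35. The thresholds themselves set these counts. With the floor at the 75th percentile, which leaves fewer genes, 137 genes were lower in heme surface cells, 73 in heme crypt cells, 851 in surface against crypt on control and 1108 on heme, and the difference of effects gave 241 and 151. With log2(2^value + 32), which shrinks dim genes, 123 genes were lower in heme surface cells, 106 higher and 52 lower in heme crypt cells, 912 lower in surface against crypt on control, and the difference of effects gave 234 and 125. Without a floor, Spearman's rho of the heme effects was 0.29, with more dim genes included. Centring on ribosomal protein genes gave 64 genes lower in heme crypt cells, 7537 higher and 120 lower in surface against crypt on control, and 6917 and 319 on heme. The ribosomal protein medians were 9.54 in control surface, 9.49 in heme surface, 10.78 in control crypt and 10.65 in heme crypt cells.

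Under that centring, in surface against crypt on control, the goblet cell median became 0.79, Lss 0.21 and Egf 0.20, and on heme Gcg became 0.044 and the smooth muscle and fibroblast median 0.72. All are shifts of the whole array. With the floor at the 75th percentile, which keeps fewer list members, the smooth muscle and fibroblast median on heme became 0.32, and that of antigen presentation and interferon in the difference of effects 0.42.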

Other observations

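Several gene families not ranked above, chosen after their values were seen, held many members past the size rule in the heme surface pool. Of 15 glutathione transferase genes, which conjugate electrophiles, 10 were at least 2-fold higher and none lower, or 66.7% against 5.63% of all genes. Among them were Gstm3 (2.12) and Gsta4 (1.82), and the control values of Gstm6 and Gstm7 lay below the floor. Gsta3, Gsta4 and Gstm1 are also on the NRF2 list, and near-identical Gstm genes may share probes. With log2(2^value + 32), 8 of these 10 remained. Among 28 ABC transporter genes, 6 were higher, including Abcc4 (3.93) and Abcc5 (1.69), and Abcg5 and Abcg8, with heme values below the floor, were lower. With log2(2^value + 32), 7 of these 8 remained, without Abcg8. Of 210 solute carrier genes, 18 were higher and 13 lower, or 14.8% against 5.63% of all genes, with the amino acid transporter genes Slc3a1 (2.40) and Slc7a9 (2.39) higher and Slc34a2 (-2.33) lower, and 24 of these 31 remained with log2(2^value + 32). In crypt cells, 4.0% of 200 solute carrier genes passed the size rule against 2.97% of all genes. Mt1 (1.14), Mt2 (1.19) and Mt4 (1.74 with log2(2^value + 32), its control value being below the floor), of 4 metallothionein genes, were higher in surface cells, as were 4 of 16 aldehyde dehydrogenase genes, among them Aldh1a7 (3.32) and Aldh1a1 (2.71).

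Of 8 interferon-induced IFIT and OAS genes, 6 were lower in heme surface cells, among them Oasl2 (-2.22) and Ifit1 (-1.35). The heme values of the other 4 lay below the floor, and with log2(2^value + 32) Ifit1bl2 differed by -1.89, Oas2 by -1.36 and Oas3 by -1.20, while Ifit2 (-0.63) did not pass the size rule. In crypt cells, 4 of 26 glycosyltransferase genes were lower and none higher, namely B3gnt6, A4gnt (-1.64), B3galt2 and Galnt15, the last a pair with heme values below the floor, and Galnt15 did not pass the size rule with log2(2^value + 32). No ribosomal protein gene of 55 in surface cells or 56 in crypt cells passed the size rule.

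The following tests on the crypt zone, immune cells and mature surface cells, the comparison of gene selections for carried-over cells and the test of carry-over on antioxidant genes were chosen only after the results they bear on were seen. Mitotic genes had a median of 1.39 in the heme crypt pool, where the stromal marker median was -0.72. A smaller share of stromal RNA would raise all epithelial genes alike, but the pan-epithelial median was -0.044 and the lower quartile of the mitotic genes 1.21. The normalization would need the mitotic median to shrink, and its lowest value under loess or ribosomal protein centring was 1.43. Centring could only raise that median, since the ribosomal protein medians were 10.78 in control and 10.65 in heme crypt cells. Loess was run on values already quantile normalized, so these alternatives do not decide on the normalization. Capture of another crypt zone cannot be told apart from an effect of heme on division, since the crypt base markers had a median of -0.36 and no record of position was used here. A higher share of dividing cells in heme crypts is consistent with these values as a hypothesis that 1 pool per diet leaves untested and counts of dividing cells along the crypt would test.

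The medians of surface colonocyte markers (0.39) and antioxidant genes (0.81) both lay above 0 in the heme crypt pool, and surface cells carried into it may account for the former. Of 79 genes at least 16-fold higher in heme surface than control crypt cells, 5.06% were not higher in heme crypt cells, as carry-over would give, but that selection favours low control crypt values. With 33 genes chosen on both diets the share was 30.3%, and with control surface over heme crypt, which favours low heme crypt values, 68.4% of 38, so that for surface genes carry-over cannot be told apart from their expression in crypt cells. For the antioxidant genes, a share of 3.87% surface RNA, the upper quartile shown by the 75 of the 79 genes outside the NRF2 list, would give the 23 members a median of 0.080, and their measured median was 0.81. The excess had a lower quartile of 0.26 and was positive for 20 of the 23. At 9.13%, the highest share of any surface colonocyte marker, its lower quartile was 0.11. Carry-over alone at these shares is argued against for the list as a set. Outside the list, Aldh1a7 showed a share of 15.1%. Me1 (14.8%), Nqo1, Akr1b8, Slc7a11, Gclc and Srxn1 lay below that, so carry-over is not excluded for them singly. Cbr3 (26.8%) and Gsta3 lay above it. Hmox1, also outside the list, showed 3.41%, below 3.87%, so carry-over could account for its crypt rise of 1.81. A response of crypt cells to heme is left as a hypothesis, to be tested by staining crypts for the antioxidant genes.

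Of 10 antigen presentation and interferon genes, 4 were lower in the heme surface pool, with Irf7 at -2.20. Fewer immune cells would lower the immune markers as well, but their median was -0.086, and the lowest of the 8 was Cd3e at -0.47. Ptprc was also lower (7.17 on control and 6.72 on heme), and Lyz2 (0.89) was higher. A smaller share of single immune cell types is therefore not excluded. H2-Aa and Cd74 are on both the immune and the interferon lists. Loss of the most mature cells would lower the surface colonocyte markers, whose median was 0.38. Of the 15 markers, 3 were at least 2-fold higher and none was lower by that rule. Ceacam20 (11.6 on control and 10.7 on heme) and Car4 (12.9 and 12.7) were lower by less, so a partial loss is not excluded. A lower interferon response of surface cells on heme is left as a hypothesis that pools of other mice would test, and differences between the few mice in these pools remain open.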
